A study of Mus musculus with 12 samples.

How the data were processed

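Gene expression was measured in BV-2 cells, an immortalised line of mouse microglia (the resident macrophages of the brain). The cells received no treatment, 20 µM curcumin (a polyphenol of turmeric), 100 ng/ml lipopolysaccharide (LPS, a bacterial cell wall component that activates Toll-like receptor 4), or both agents together. The labels give 6 h for the treatments and state neither a time for the untreated cells nor a vehicle. Each of the 4 groups has 3 arrays, numbered by replicate in the labels. Per the labels' protocols, total RNA was purified on columns, amplified, labelled with the dye Cy3 and hybridised to one-colour Agilent arrays. Per the file headers, the arrays lie on 3 slides of 4 arrays. Slide, scan and replicate number coincide, each slide holds 1 array of each group, and every group always takes the same position on its slide. Group and position therefore cannot be told apart, while slide can be examined as a batch.

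The deposited scanner files hold spot intensities on a linear scale, extracted by the authors with Agilent Feature Extraction, version 10.5.1.1 per the file headers and version 9.1 per the submitters' processing notes. The processed signal used here is an intensity from which background had already been subtracted by that software, per the file headers. The value table deposited with the series holds intensities that equalled this processed signal, spot by spot, within 0.397%, and served as an alternative input. Each array carries 45018 spots, of which 1639 are controls, and the remaining spots represent 41174 distinct probes. The files give accessions and no gene symbols, so probes were named through RefSeq accessions in a gene annotation of assembly GRCm38.p6, used for names and gene order only. Of the probes, 25097 matched a symbol (17305 distinct symbols) and 16077 did not. Probes without a symbol were tested and counted as unnamed transcripts and are not discussed singly. Rigi stands in that annotation as Ddx58. Il10 was on the list of genes to be given for every comparison and is not among the genes tested.

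The log2 of the processed signal minus each array's 75th percentile over non-control spots was the expression value. Spots marked by the software as outliers were dropped, spots of a probe were averaged, and 1 probe stood for a gene, the one with the highest mean signal over the 12 arrays. A probe was tested where it was well above background on all 3 arrays of at least 1 group, which left 19314 genes and transcripts, 12655 of them with a symbol. Of the tested genes, 4849 had more than 1 tested probe. Genes whose probes were called in opposite directions numbered 0, 78, 11, 0 and 0 for the 5 comparisons in the order below. Of the genes singled out, Slc39a14 is such a gene for curcumin versus untreated, and Insig1 for LPS+curcumin versus LPS. A linear model with 4 group means over all 12 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with jsonlite 2.0.0 and data.table (version 1.17.8) for reading files. The comparisons were LPS versus untreated, curcumin versus untreated, LPS+curcumin versus LPS, LPS+curcumin versus curcumin, and their interaction, which is the effect of curcumin with LPS minus its effect without LPS. P-values are two-sided, adjusted by Benjamini-Hochberg over the genes tested, and a gene was called changed at an adjusted p below 0.05. Errors of log2 fold changes are the standard errors of this fit, with 3 arrays per group.

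Where no probe of a gene was well above background on any array of a group, only a bound can be given. The bound sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Such a change is written as at least N-fold.

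The 26 gene lists, the tests and the rule for named genes were fixed before the data were examined. Lists were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the lists within a comparison, and again with the correlation estimated from the data. Camera compares the genes of a list with all other genes tested, so a list whose genes rise less than the other genes is called lower. Members were also counted as called when adjusted over all genes and when adjusted over the list alone. Named genes for a comparison had an adjusted p below 0.05, all 3 arrays of one group above all 3 of the other, a signal well above background on at least 2 of 3 arrays in both groups, and a proper symbol. From these the 10 highest and 10 lowest fold changes were taken (5 and 5 for LPS+curcumin versus curcumin and for the interaction). The 3 highest bounds per direction and up to 4 called members per list with the smallest adjusted p were added. Tnf, Il1b, Il6, Nos2, Ptgs2, Ccl2, Tlr2, Tlr4, Arg1, Hmox1 and Nqo1 are given whatever their test showed. Some genes that this rule takes are not reported here. The transcripts of other tissues named in the closing section come from lists made after the data were examined.

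Alternatives planned before the data were examined were background correction by normexp (offset 50), quantile normalization, scaling on the median of all probes, no filter on dim probes, a filter on all 12 arrays, the replicate number (the slide) as a block, the mean over the probes of a gene, a trend with robust eBayes, the value table as input, fits of only the groups compared, and leaving out each array and each replicate in turn (for the gene lists, each replicate). Normexp used the median spot and background signals, since no mean signal was used here. Added after the data were seen were scaling on 7 of the 10 spike-in probes (added RNA of known amount), scaling on the median of the 21016 probes well above background on all 12 arrays, keeping the spots marked as outliers, leaving out each array in turn for the gene lists, leaving LPS+curcumin replicate 1 out of every result, exchanging labels within slides for the 75th percentile relative to the spike-in probes, and correlating the curcumin effect without LPS on one slide with that with LPS on another. Genes called in the same direction on all 5 scalings (75th percentile, quantile, median, spike-in and always detected probes) were counted, which was also decided after the data were seen.

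The pipeline was tested on simulated data, in which 200 of the 19314 genes were changed in the design of this study. With LPS versus untreated, 73% of simulated 4-fold changes and 18% of simulated 2-fold changes were recovered with the right sign, and 7 unchanged genes were called. For the interaction these shares were 39% and 2%, and 6 unchanged genes were called. Simulated arrays without a curcumin effect gave the values that shared arrays produce by themselves. Their noise was drawn separately for each array and holds no noise shared by a slide. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision.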

Results

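The data are 12 one-colour expression arrays of BV-2 mouse microglial cells, 3 each of untreated cells, cells with 20 µM curcumin, cells with 100 ng/ml LPS, and cells with both (LPS+curcumin). The study set out to define how curcumin changes the transcriptome of resting and activated microglia. Between 58.0% and 65.9% of the spots were well above background on each array, no spot was saturated, and the 75th percentile of the signal lay between 304 and 979. Correlations between arrays of a group ran from 0.932 to 0.997. LPS+curcumin replicate 1 stood apart from the other 2 arrays of its group, with a mean correlation of 0.982 with the LPS arrays and 0.950 with the curcumin arrays. The other 2 correlated with the curcumin arrays at 0.984 and 0.985, and with the LPS arrays at 0.940 and 0.923. LPS+curcumin replicate 2 carried 1594 spots marked as outliers, against at most 163 on any other array.

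**Figure D1:**
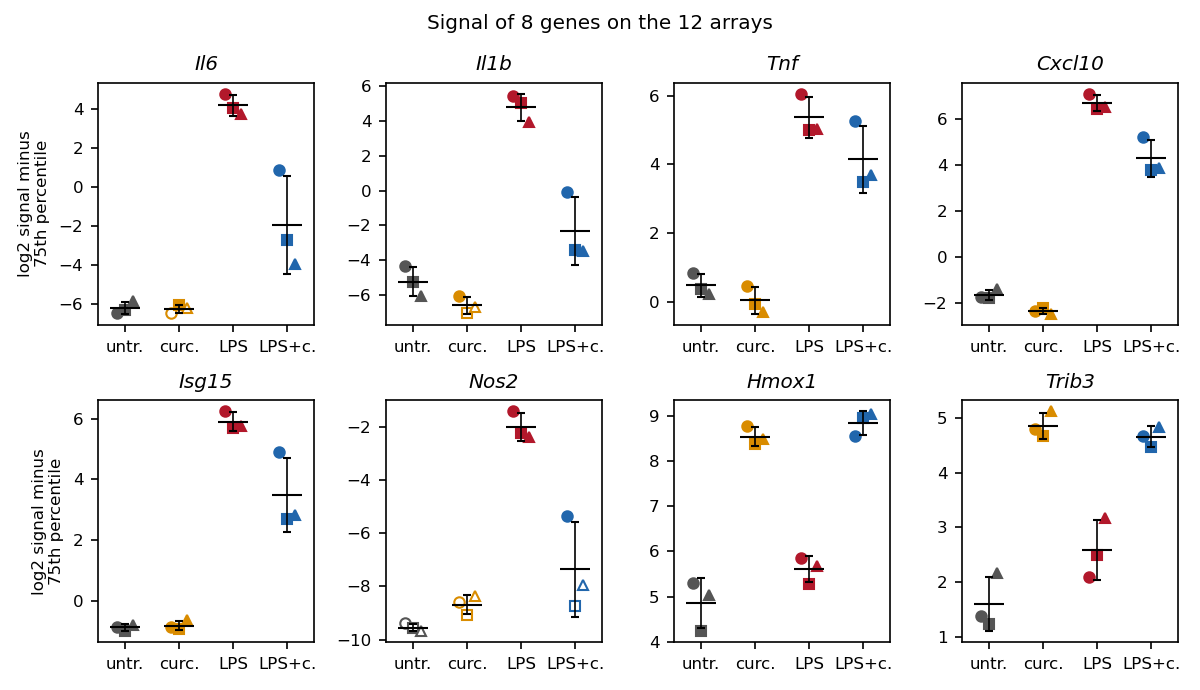
Log2 signal minus the array's 75th percentile for 8 genes on the 12 arrays (untr., untreated; curc., curcumin; LPS+c., LPS+curcumin); circles, squares and triangles are replicates 1, 2 and 3, filled where the spot was well above background, and black bars are the mean and SD of 3 arrays. Il6, Il1b, Cxcl10, Isg15 and Nos2 lay lower on the LPS+curcumin arrays than on the LPS arrays, least so on LPS+curcumin replicate 1, and Hmox1 and Trib3 were high on all arrays with curcumin.

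LPS switched on the inflammatory and interferon programmes of the cells. The cytokine genes Il6 and Il1b rose most among the genes measured in both groups, by 10.40 ± 0.91 and 10.03 ± 0.82 on the log2 scale (SE, n = 3 per group; adjusted p = 5.99e-05 and 3.85e-05), which is 1351-fold and 1048-fold. Csf3, which encodes the granulocyte growth factor G-CSF, rose at least 1617-fold from background, and the neutrophil chemokine gene Cxcl2 at least 274-fold. Tnf rose by 4.88 ± 0.46, Ptgs2 (cyclooxygenase 2) by 5.92 ± 0.74 and the monocyte chemokine gene Ccl2 by 3.89 ± 0.55. Nos2, the inducible nitric oxide synthase, rose at least 41.3-fold. The signal of Il6 was higher with LPS on each slide, by 11.24, 10.37 and 9.60.

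Of 19314 genes and transcripts tested with limma, 1107 changed, 796 higher and 311 lower, and 717 rose and 232 fell at least 2-fold. On quantile and spike-in scaling 613 were higher against 399 lower, and 361 against 292, and 334 higher and 118 lower calls held on all 5 scalings. The count was 682, 577 and 679 without untreated replicates 1, 2 and 3, 605 and 691 without LPS replicates 1 and 2, 1814 without LPS+curcumin replicate 1, which enters through the shared spread, and 197 with normexp. Of 78 named genes called, 58 were called whichever single array was left out, and the genes named for this comparison are among these unless stated.

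Of 38 interferon-stimulated genes measured, 37 rose and 1 did not pass (38 adjusted over the list alone), with a median of 4.90 and medians of 4.97, 4.57 and 5.18 within the slides (camera, adjusted p = 1.39e-57). They included the antiviral genes Isg15 (6.79 ± 0.47), Isg20 (5.78 ± 0.24) and Zbp1 (7.85 ± 0.60). Of 25 inflammatory cytokines and mediators, 22 rose (25 adjusted over the list alone), with a median of 4.58 (camera, adjusted p = 3.07e-37). Of 18 chemokines, 16 rose (17 adjusted over the list alone), among them Cxcl10 by 8.33 ± 0.35 and Ccl5 by 7.26 ± 0.37, with a list median of 3.94, or 3.12 with undetected genes at their bound (camera, adjusted p = 2.45e-32). Of 19 NF-kB subunits and feedback genes, 17 rose (18 adjusted over the list alone), with a median of 2.40 (camera, adjusted p = 5.07e-26), including the adaptor gene Traf1 (9.56 ± 0.76), Nfkbiz (4.77 ± 0.32) and the adhesion gene Icam1 (2.86 ± 0.30). These 4 lists were also called with an estimated correlation (adjusted p = 0.0401, 0.0215, 0.0195 and 0.0358 in this order). On spike-in scaling 26, 17, 13 and 9 of their members were higher, with medians of 4.62, 4.30, 3.66 and 2.13, and 26, 17, 12 and 8 higher calls held on all 5 scalings.

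Smaller shifts were called for 7 more lists at the preset correlation and for none of them with an estimated one. Of 18 antigen presentation genes 9 rose (13 adjusted over the list alone), with 1 call that held on all 5 scalings and a median of 0.94, or 0.66 on spike-in scaling (adjusted p = 1.05e-11, and adjusted p = 0.101 with an estimated correlation), including the peptide transporter genes Tap1 (2.35 ± 0.40) and Tap2 (1.27 ± 0.23), whose calls were lost on spike-in scaling. Of 24 immediate early genes 7 rose (9 adjusted over the list alone; 3 on all 5 scalings), with a median of 0.68, or 0.41 on spike-in scaling (adjusted p = 4.84e-06, and adjusted p = 0.101 with an estimated correlation), including Ier3 (2.70 ± 0.25) and Phlda1 (3.98 ± 0.41). Of 19 Toll-like receptor (TLR) genes and adaptors 5 rose (7 adjusted over the list alone), calls that were all lost on spike-in scaling in limma, with a median of 0.33, or 0.06 on spike-in scaling (adjusted p = 0.0119, and adjusted p = 0.484 with an estimated correlation). Of 38 adhesion, migration and matrix genes 8 rose and 1 fell (10 and 4 adjusted over the list alone; 5 and 1 on all 5 scalings), with a median of 0.36, or 0.08 on spike-in scaling and 0.55 without untreated replicate 3 (adjusted p = 0.000464). The collagenase gene Mmp13 rose by 5.36 ± 0.54, Mmp14 rose at least 13.8-fold, and the chemokine receptor gene Cxcr4 fell by 3.82 ± 0.40. Of 24 genes of the ATF4 stress response 3 rose (5 adjusted over the list alone; 1 on all 5 scalings), with a median of 0.31, or 0.03 on spike-in scaling and 0.48 without untreated replicate 3 (adjusted p = 0.000604). DNA replication genes had a median of −0.43, or −0.71 on spike-in scaling (adjusted p = 3.8e-06), with 1 of 25 called lower (3 on spike-in scaling). G2/M genes had a median of −0.15, or −0.43 on spike-in scaling (adjusted p = 0.0256, and adjusted p = 0.127 without LPS replicate 2, where the median was −0.12), with 0 of 25 called in limma. Without LPS+curcumin replicate 1, 5 ATF4 genes rose and 3 DNA replication genes fell. With an estimated correlation, the adjusted p = 0.45 for adhesion, ATF4 and DNA replication genes and the adjusted p = 0.452 for G2/M genes.

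Among genes outside the inflammatory lists, the death receptor gene Fas rose by 5.95 ± 0.60 and the interleukin 1 receptor antagonist gene Il1rn by 4.48 ± 0.48. Besides Cxcr4, genes among the lowest changes were Scel (−3.27 ± 0.44), the sialyltransferase gene St6gal1 (−2.95 ± 0.28), the transcription factor gene Foxo6 (−2.88 ± 0.31) and the lipin gene Lpin1 (−2.74 ± 0.35). Hmox1, Nqo1, Tlr4 and Arg1 had changes of 0.75 ± 0.29, 0.35 ± 0.42, −0.96 ± 0.42 and −0.88 ± 0.62, with adjusted p = 0.205, 0.903, 0.299 and 0.646. Tlr2 had a change of 2.62 ± 0.83 (adjusted p = 0.107) and was called with the slide as a block (adjusted p = 0.011).

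On all 5 scalings, curcumin alone raised 6 of 24 genes of the ATF4 stress response and 1 of 32 NRF2 targets, and lowered 7 of 19 TLR genes and adaptors. Of all 19314 genes and transcripts 1293 were higher and 1261 lower on all 5 scalings. The share of NRF2 targets thus lay below that of all genes. Hmox1, which encodes the haem-degrading enzyme heme oxygenase 1, rose 12.9-fold, by 3.69 ± 0.29 (SE, n = 3 per group; adjusted p = 7.38e-05), and by 3.48, 4.14 and 3.44 within the slides. The stress-induced genes Ddit3, Trib3 and Sesn2 rose by 3.38 ± 0.34, 3.27 ± 0.31 and 2.99 ± 0.38. The LPS receptor gene Tlr4 fell by 2.25 ± 0.42 (adjusted p = 0.00418), Tlr7 by 1.83 ± 0.33, and the oxysterol receptor gene Gpr183 by 4.46 ± 0.75. The calls of Hmox1, Ddit3, Trib3, Sesn2, Tlr4, Tlr7 and Gpr183 held on all 5 scalings and with any single array left out.

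For many genes the direction of the change with curcumin depended on how the arrays were scaled. The 75th percentile lay 1.11 lower on the curcumin arrays than on the untreated arrays on the log2 scale relative to the spike-in probes (−2.19 ± 0.153 against −1.09 ± 0.184, SD, n = 3). Over both pairs of groups, arrays with and without curcumin differed by −0.91 (exact permutation test within the groups with and without LPS, two-sided p = 0.015, 6 arrays per side). Within slides 1, 2 and 3 the difference was −1.06, −1.20 and −1.05 without LPS and 0.117, −0.859 and −1.42 with LPS, so that LPS+curcumin replicate 1 went the other way. Exchanging labels within slides gave an exact two-sided p = 0.0625, where the smallest possible is 0.0312. After scaling on the 75th percentile the median change of all genes was 0.41, and it was −0.01 on quantile, −0.42 on median, −0.69 on spike-in and 0.42 on always detected probes. Changes with curcumin are relative to this shift.

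With limma 5632 genes and transcripts changed, 4226 higher and 1406 lower. The split was 2233 higher and 2005 lower on quantile, 1578 and 4848 on median, and 1395 and 8404 on spike-in scaling, and 1293 higher and 1261 lower calls held on all 5 scalings. The count was 3079, 2759 and 2889 without untreated replicates 1, 2 and 3, 3322 and 2579 without curcumin replicates 2 and 3, 9694 without LPS+curcumin replicate 1, and 872 with normexp. Without all 4 arrays of replicate 2 it was 20. Of 103 named genes called, 58 were called whichever array was left out.

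**Figure D2:**
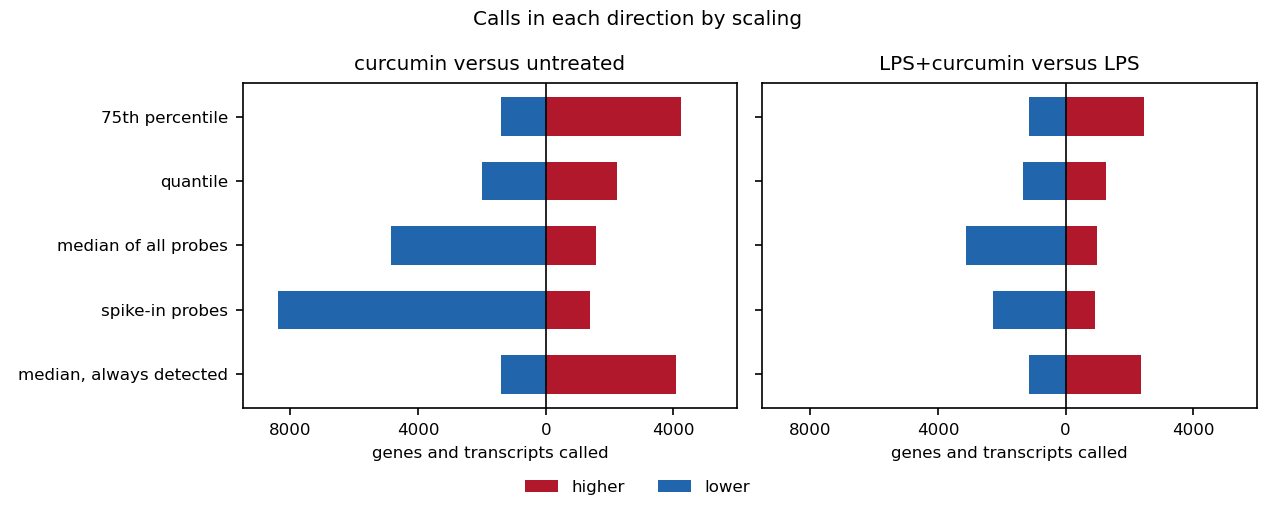
Number of genes and transcripts called higher (red, right) or lower (blue, left) in 2 comparisons on 5 scalings of the arrays. In curcumin versus untreated 4226 were higher on the 75th percentile and 1395 on spike-in probes, and in LPS+curcumin versus LPS 2460 and 937, so that the main direction turned with the scaling.

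Of 32 targets of NRF2, the transcription factor of the antioxidant response, 14 rose and 18 did not pass (19 adjusted over the list alone), and 1 call, that of Hmox1, held on all 5 scalings. Their median of 0.73 lay above the 0.41 of all genes (camera, adjusted p = 0.00468, and adjusted p = 0.109 with an estimated correlation). It was 0.60, 0.76 and 0.80 within the slides, and it turned to −0.37 on spike-in and −0.10 on median scaling. The call was lost when all arrays of replicate 1 were left out (median 0.79, adjusted p = 0.051). Besides Hmox1, the haem transporter gene Slc48a1 rose by 1.32 ± 0.18, Sqstm1 by 1.51 ± 0.22 and the glutathione reductase gene Gsr by 1.33 ± 0.24, which were 0.21, 0.41 and 0.22 on spike-in scaling and not called there. Nqo1 rose by 1.42 ± 0.42 (adjusted p = 0.0308), which was 0.31 on spike-in scaling and not called there, and the call was also lost without untreated replicate 1 or 2 or curcumin replicate 2 or 3, with an adjusted p of up to 0.11. Of 24 genes of the ATF4 stress response 14 rose (16 adjusted over the list alone; 6 on all 5 scalings), with a median of 0.92 (adjusted p = 0.0025, and adjusted p = 0.835 with an estimated correlation) that was −0.18 on spike-in scaling.

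Of 19 TLR genes and adaptors 7 fell and 1 rose (8 and 2 adjusted over the list alone; the 7 lower calls on all 5 scalings), with a median of −0.74 that was negative on every scaling (−1.84 with 17 lower on spike-in scaling; adjusted p = 6.23e-06, and adjusted p = 0.762 with an estimated correlation). The TLR-related receptor gene Cd180 fell by 1.70 ± 0.31. Of 26 microglia and macrophage identity genes 6 fell and 2 rose (6 and 2 adjusted over the list alone; the 6 lower calls on all 5 scalings). The list was called lower although its median was 0.03 (−1.08 on spike-in scaling), since the median of all genes was higher (adjusted p = 0.0418, adjusted p = 0.835 with an estimated correlation, and adjusted p = 0.057 with the slide as a block). Over single arrays left out this median ran from −0.17 to 0.38, and the call was lost without untreated replicate 1 or curcumin replicate 2 or 3, with an adjusted p of up to 0.239. Its members with lower calls on all 5 scalings included the purinergic receptor gene P2ry13 (−3.48 ± 0.51) and the transcription factor gene Irf8 (−1.74 ± 0.28). The direction of P2ry13 was reversed with normexp (0.77). Gas6 rose by 2.44 ± 0.43, a call that did not hold on all 5 scalings. Interferon-stimulated genes (3 of 38 higher, 1 adjusted over the list alone) had a median of −0.32 and G2/M genes (0 of 25 called in limma) one of −0.04, and both lists were called lower (adjusted p = 0.0418 each, and adjusted p = 0.835 with an estimated correlation). The interferon call was lost without untreated replicate 1 or curcumin replicate 2 or 3 (median over single arrays left out −0.38 to −0.22, adjusted p of up to 0.101), and the G2/M call without untreated replicate 1 or curcumin replicate 1 or 2 (−0.13 to −0.03, adjusted p of up to 0.0824). When LPS+curcumin replicate 1, which enters through the shared spread, was left out, 6 interferon-stimulated genes rose and 15 fell, 2 G2/M genes rose and 5 fell, and 2 TLR genes rose and 11 fell. On spike-in scaling 22 of 25 G2/M genes were lower (median −1.14, adjusted p = 0.00597), and the interferon list, with 1 gene higher, 5 lower and a median of −1.42, was not called (adjusted p = 0.919). Isg20 rose by 2.52 ± 0.24 (1.42 on spike-in scaling), a call that held on all 5 scalings.

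No other list was called on the 75th percentile. Of 23 heat shock genes 8 rose (8 adjusted over the list alone; 1 on all 5 scalings), with a median of 0.68 that was −0.42 on spike-in scaling (adjusted p = 0.127). The inducible chaperone gene Hspa1a rose at least 18.1-fold. Of 18 antigen presentation genes 6 rose (2 on all 5 scalings), including Ciita, the master regulator of MHC class II genes (4.66 ± 0.59), and H2-DMa (3.44 ± 0.36), both called on all 5 scalings (list median 0.59, −0.51 on spike-in scaling, adjusted p = 0.127). Of 19 endoplasmic reticulum chaperones 5 rose (4 adjusted over the list alone), calls that were all lost on spike-in scaling, with a median of 0.62 that was −0.48 on spike-in scaling (adjusted p = 0.127). Among 24 immediate early genes 5 rose and 3 fell (2 and 3 on all 5 scalings), with Nr4a2 at 3.03 ± 0.51, Fos at −1.67 ± 0.33 and Dusp6 at −2.29 ± 0.35 (list adjusted p = 0.127). With LPS+curcumin replicate 1 left out, 15 heat shock genes and 11 chaperones rose, and 6 immediate early genes rose and 6 fell.

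Cytokine genes did not move as one. Of 25 inflammatory cytokines and mediators 3 rose and 1 fell (1 and 1 on all 5 scalings; median 0.28, tested in the lower direction, adjusted p = 0.314), and of 18 chemokines 2 rose and 4 fell (the 4 lower calls on all 5 scalings; median 0.47, tested in the lower direction, adjusted p = 0.166). With undetected genes at their bound both medians were 0, and on spike-in scaling they were −0.82 and −0.64. Csf3 rose at least 9.49-fold, Ccl3 fell by 1.63 ± 0.24 and Ccl7 by 3.07 ± 0.71. Tnf, Il6, Il1b, Ptgs2, Ccl2 and Tlr2 were at −0.44 ± 0.46, −0.04 ± 0.91, −1.37 ± 0.82, −1.104 ± 0.740, −1.05 ± 0.55 and −2.33 ± 0.83, with adjusted p = 0.453, 0.976, 0.201, 0.247, 0.147 and 0.0541. Tlr2 was called with the slide as a block (adjusted p = 0.008) and on spike-in scaling (adjusted p = 0.0201). Arg1 was at 0.79 ± 0.62, was negative on spike-in scaling and was not called (adjusted p = 0.316). Nos2 was not well above background on any array of either group. Among 19 NF-kB genes 3 rose, calls lost on spike-in scaling, where 7 fell, with a median of −0.31 (−1.42 on spike-in scaling; adjusted p = 0.158). In the fit without LPS+curcumin replicate 1, 6 cytokines rose and 6 fell, and 5 NF-kB genes rose and 3 fell.

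Among genes measured in both groups, the highest fold changes with curcumin were in Lin7b (7.40 ± 0.89), the collectin gene Colec11 (7.28 ± 0.86), Cfap53 (6.13 ± 0.90) and the interferon gene Ifna12 (6.10 ± 0.99). Gramd1c, the AMP deaminase gene Ampd1 and the hexokinase-like gene Hkdc1 rose from background at least 250-fold, 243-fold and 200-fold. Of 12996 genes and transcripts not well above background on any untreated array, 678 were well above it on all 3 curcumin arrays and 143 on all 3 LPS arrays. Of the 678, 670 were called higher (15.9% of all higher calls), all by at least 2-fold, 190 of them by at least 10-fold, with a median bound of 5.75-fold (quartiles 3.74 and 11.7). Of these 670, 90.6% and 85.7% were well above background on LPS+curcumin replicates 2 and 3, and 19.0% on replicate 1. The background they had in untreated cells is that of the array, so their level there is not known.

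**Figure D3:**
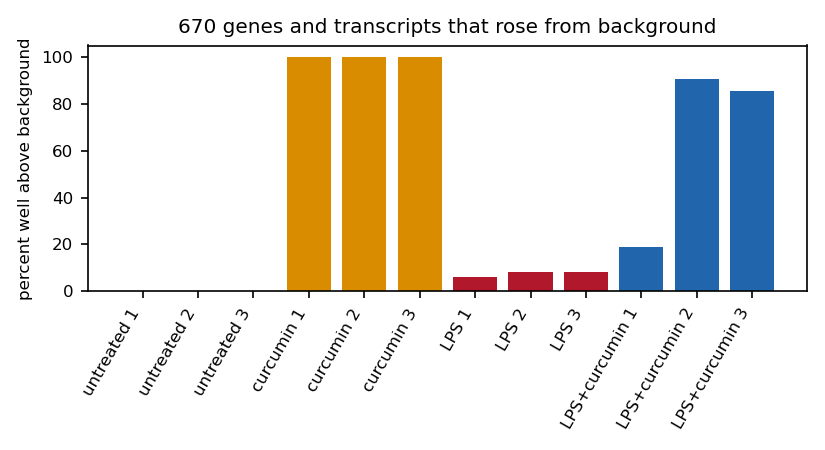
Percent of the 670 genes and transcripts that rose from background with curcumin which were well above background on each of the 12 arrays. By their selection they are at 0 on the untreated and at 100 on the curcumin arrays, and they lie between 6.12% and 8.36% on the LPS arrays, at 19.0% on LPS+curcumin replicate 1, and at 90.6% and 85.7% on replicates 2 and 3.

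In LPS-treated cells curcumin lowered much of the LPS response. Il1b fell 138-fold, by 7.11 ± 0.82 on the log2 scale (SE, n = 3 per group; adjusted p = 0.0008), Il6 by 6.13 ± 0.91 (70.1-fold), Csf3 by 6.23 ± 0.72, Nos2 by 5.33 ± 0.67 and Ptgs2 by 3.78 ± 0.74. The antiviral gene Zbp1 fell by 6.32 ± 0.60 and the interferon regulatory factor gene Irf7 by 4.09 ± 0.47. Hmox1 rose 9.51-fold, by 3.25 ± 0.29. Tnf differed by −1.21 ± 0.46, which did not pass (adjusted p = 0.0858) and passed with the slide as a block (adjusted p = 0.0103). All genes named here with a call kept it on all 5 scalings and with any single array left out.

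With limma 3618 genes and transcripts changed, 2460 higher and 1158 lower, with a median of all genes of 0.32. The split was 1257 higher and 1329 lower on quantile (median of all genes 0.04), 1000 and 3122 on median (−0.41), and 937 and 2274 on spike-in scaling (−0.40), and 643 higher and 1014 lower calls held on all 5 scalings. The count was 1585, 1320 and 1603 without LPS replicates 1, 2 and 3, 10789, 1092 and 2197 without LPS+curcumin replicates 1, 2 and 3, 5575 with the slide as a block, and 89 with normexp. Without all arrays of replicate 2 or replicate 3 it was 9 and 242. Of 101 named genes called, 65 were called whichever array was left out.

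Of 38 interferon-stimulated genes 36 fell (38 adjusted over the list alone), with a median of −3.58 (camera, adjusted p = 4.81e-36, and adjusted p = 0.128 with an estimated correlation). Within the slides this median was −1.97, −4.02 and −4.91. Dhx58 and Isg20 fell by 3.07 ± 0.31 and 3.17 ± 0.24. Of 25 inflammatory cytokines and mediators 17 fell and 1 rose (20 and 1 adjusted over the list alone), with a median of −2.88, and −2.04, −3.16 and −2.25 within the slides (adjusted p = 9.04e-17, and adjusted p = 0.128 with an estimated correlation). Of 18 chemokines 10 fell (15 adjusted over the list alone), with a median of −1.79, and −2.30, −2.46 and −0.84 within the slides (adjusted p = 4.47e-13, and adjusted p = 0.128 with an estimated correlation). Ccl7 fell by 6.26 ± 0.71, Ccl12 by 3.86 ± 0.55, Ccl2 by 3.56 ± 0.55 and Cxcl10 by 2.41 ± 0.35. Of 19 NF-kB subunits and feedback genes 5 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of −0.91 (adjusted p = 4.79e-06, and adjusted p = 0.399 with an estimated correlation), Tnip3 among them by 4.54 ± 0.80. On spike-in scaling the medians of these 4 lists were −4.30, −3.60, −2.51 and −1.63, with 37, 18, 16 and 8 genes lower. Without LPS+curcumin replicate 1 they were −4.68, −3.05, −1.84 and −1.16, with 38, 20, 15 and 11 genes lower, and without replicate 3 of that group the cytokine median was −1.90.

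Of 19 TLR genes and adaptors 10 fell (13 fell and 2 rose adjusted over the list alone), with a median of −1.15 (adjusted p = 2.85e-08, and adjusted p = 0.191 with an estimated correlation). Tlr7 fell by 2.50 ± 0.33, Tlr3 by 4.22 ± 0.66 and Irak3 by 2.80 ± 0.51. Tlr2 fell by 2.83 ± 0.83 (adjusted p = 0.038). This call was lost without any 1 of the LPS arrays or without LPS+curcumin replicate 2 or 3, with an adjusted p of up to 0.143. Tlr4 was at −1.15 ± 0.42 (adjusted p = 0.0777, and adjusted p = 0.046 with the slide as a block). Of 38 adhesion, migration and matrix genes 9 fell and 1 rose (9 and 2 adjusted over the list alone), with a median of −0.37, or −0.18 with undetected genes at their bound (adjusted p = 8.59e-05, and adjusted p = 0.475 with an estimated correlation). Slide 3 alone gave 0.50. The fractalkine receptor gene Cx3cr1 fell by 4.59 ± 0.62 and the matrix protease gene Mmp14 by 2.69 ± 0.43. Of 24 immediate early genes 6 fell and 3 rose (7 and 4 adjusted over the list alone), with a median of −0.52 (adjusted p = 0.00398, adjusted p = 0.399 with an estimated correlation, and adjusted p = 0.153 on spike-in scaling), with Fos at −1.95 ± 0.33 and Nr4a2 at 3.16 ± 0.51. Of 18 antigen presentation genes 3 fell and 1 rose (4 and 1 adjusted over the list alone), with a median of −0.12 that was 0.32 on slide 3 (adjusted p = 0.0028, and adjusted p = 0.576 with an estimated correlation). Tap1 fell by 2.46 ± 0.40 and H2-DMa rose by 2.63 ± 0.36. On spike-in scaling the medians of the TLR, adhesion, immediate early and antigen presentation lists were −1.87, −1.09, −1.24 and −0.84, with 10, 15, 9 and 6 genes lower. They were −1.53, −0.19, −0.62 and −0.08, with 16, 12, 12 and 5 genes lower and 1, 8, 5 and 2 higher, without LPS+curcumin replicate 1. Over all single arrays left out they ran from −1.53 to −0.81, from −0.53 to −0.07, from −0.65 to −0.34 and from −0.30 to −0.02, the adhesion and antigen presentation medians lying nearest 0 without LPS+curcumin replicate 2 and the immediate early median without LPS replicate 1, and the 4 calls held. When all arrays of replicate 1 were left out, the antigen presentation list was not called (median 0.05, adjusted p = 0.051).

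In LPS-treated cells 1 NRF2 target (Hmox1), 3 of 24 ATF4 genes and 2 of 23 heat shock genes rose on all 5 scalings. Of all 19314 genes and transcripts 643 did so, a share no lower than that of the NRF2 targets. Of 32 NRF2 targets 13 rose (17 adjusted over the list alone), with a median of 0.69 (0.51, 0.67 and 0.78 within the slides) against 0.32 for all genes, and −0.02 on spike-in scaling. The list was called at the preset correlation and with an estimated one (adjusted p = 0.000148 and 0.04), and not without LPS+curcumin replicate 1 (adjusted p = 0.0608), where the median was 0.82 against 0.49 for all genes and 22 rose. The glutathione synthesis gene Gclm rose by 1.84 ± 0.32 and Slc48a1 by 1.52 ± 0.18, neither of them called on spike-in scaling. Nqo1 rose by 1.43 ± 0.42 (adjusted p = 0.04), a call lost on spike-in scaling (0.71) and without any 1 of the LPS arrays or without LPS+curcumin replicate 2 or 3, with an adjusted p of up to 0.134. Of 24 ATF4 genes 8 rose (13 adjusted over the list alone; median 0.76), of 23 heat shock genes 4 (4 adjusted over the list alone; 0.51) and of 19 endoplasmic reticulum chaperones 4 (6 adjusted over the list alone; 0.58). On spike-in scaling these medians were 0.04, −0.21 and −0.14, and the heat shock and chaperone lists were not called (adjusted p = 0.318 and 0.153). These 3 lists were called at the preset correlation (adjusted p = 0.00598, 0.0412 and 0.00638). With an estimated correlation the adjusted p = 0.613, 0.737 and 0.5, and without LPS+curcumin replicate 1 the adjusted p = 0.106, 0.0766 and 0.117, with higher medians of 0.90, 0.76 and 0.81 (all genes 0.49) and 15, 14 and 10 genes rising. The heat shock call was also lost without LPS replicate 2 or LPS+curcumin replicate 3 (lowest median 0.33, adjusted p of up to 0.117). Trib3 and Sesn2 rose by 2.08 ± 0.31 and 2.30 ± 0.38 (1.36 and 1.58 on spike-in scaling), calls that held on all 5 scalings, and Hspa1a rose at least 31.6-fold. Of 26 identity genes 7 fell and 2 rose (7 and 3 adjusted over the list alone), called lower with a median of 0.06, or −0.67 on spike-in scaling (adjusted p = 0.0446). That call was lost with an estimated correlation (adjusted p = 0.737), with the slide as a block (adjusted p = 0.0702) and without LPS replicate 1 or LPS+curcumin replicate 1 or 3 (adjusted p of up to 0.291), while the median ran from −0.14 to 0.14 over single arrays left out. P2ry13 fell at least 2.61-fold, a direction that was reversed with normexp (0.16), and Irf8 fell by 1.93 ± 0.28. Arg1 was at 0.89 ± 0.62 (adjusted p = 0.29), a direction that did not hold on all scalings.

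**Figure D4:**
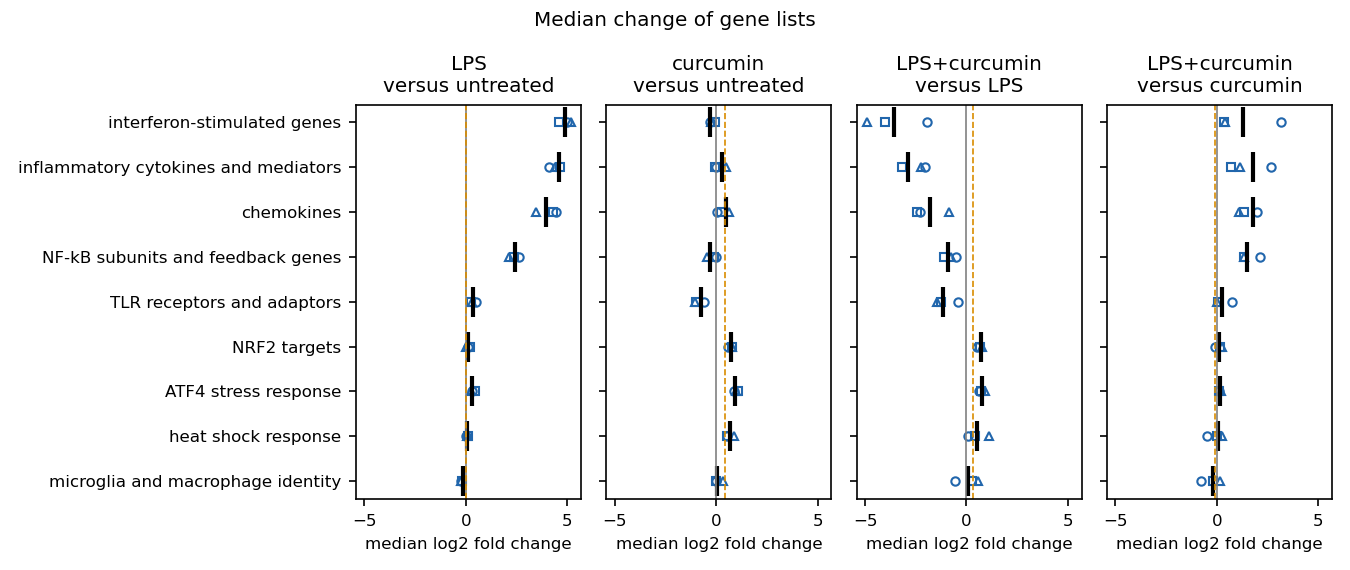
Median log2 fold change of 9 gene lists in 4 comparisons; black bars are medians over the fitted genes, open circles, squares and triangles the medians within slides 1, 2 and 3, and the dashed orange line the median of all genes. Interferon-stimulated genes stood at 4.90 with LPS and at −3.58 in LPS+curcumin versus LPS, and NRF2 targets at 0.73 and 0.69 with curcumin, medians that were −0.37 and −0.02 on spike-in scaling.

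The genes that LPS moved were then followed under LPS+curcumin. Of the 717 genes that LPS raised at least 2-fold, 430 were called lower in LPS+curcumin than in LPS and 19 higher. Independent calls would overlap in 43.0 genes. In 20 simulations without a curcumin effect, in which the shared LPS arrays were kept, 0 induced genes were called lower. With no gene changed by curcumin the adjustment leaves few calls, so this 0 does not measure selection. The median change of the induced genes averaged −0.089 in the simulations. The median change of the 717 genes was −1.40, and −1.18, −1.70 and −1.31 within the slides, and it stayed negative on every scaling and with normexp, where it was −0.68. Of the 232 genes that LPS lowered, 63 were called higher and 4 lower. Of all 19314 genes and transcripts 2460 were called higher and 1158 lower. The median change of the 232 genes was 0.54, against 0.32 for all genes, so part of their rise is the general shift. The 430 became 252 and 280 without LPS replicates 1 and 2, 276 without LPS+curcumin replicate 2, 635 of 922 induced genes without LPS+curcumin replicate 1, and 62 with normexp. The 63 became 41, 30 and 31 on quantile, median and spike-in scaling, 108 with the slide as a block and 1 with normexp. They became 36 and 30 without untreated replicates 1 and 2, 32 and 20 without LPS replicates 1 and 2, and 163 and 28 without LPS+curcumin replicates 1 and 2. The median LPS effect of the induced genes was 2.38 without and 0.57 with curcumin. The latter is measured against curcumin alone, where 165 of the 717 genes were called higher and 24 lower than in untreated cells. Of all 19314 genes and transcripts 4226 were called higher and 1406 lower there. The share of the 717 called higher was thus close to that of all genes. A level raised by curcumin alone also makes the LPS effect with curcumin, and the slope below, smaller. Across the 717 and 232 genes the slope of the LPS effect with curcumin on that without it was 0.285, with r = 0.677 and rho = 0.673 across genes, which are not independent replicates. The slope was 0.462, 0.191 and 0.191 within the slides and 0.184 without LPS+curcumin replicate 1. Simulated arrays without a curcumin effect gave a mean slope of 0.913.

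**Figure D5:**
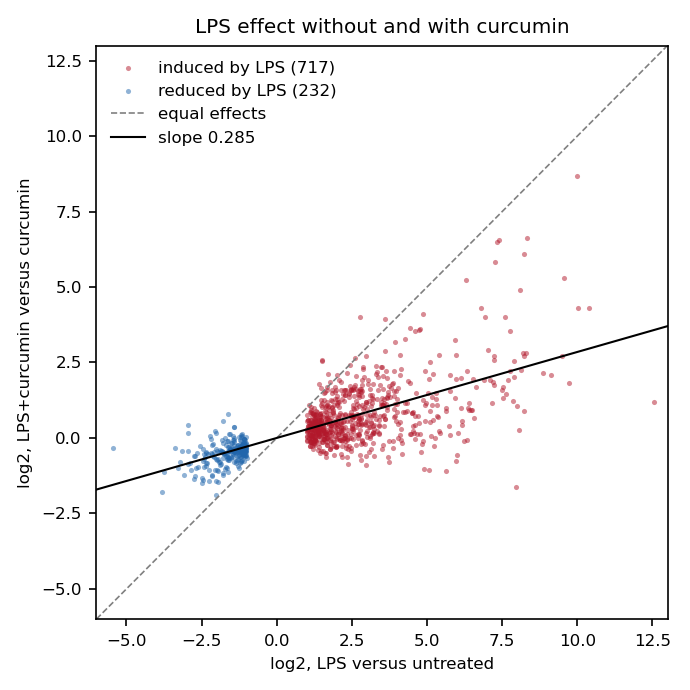
LPS effect without curcumin (x axis) and with curcumin (y axis), both log2 fold changes, for 717 genes raised (red) and 232 lowered (blue) at least 2-fold by LPS. The dashed line marks equal effects and the solid line the slope of 0.285.

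In cells with curcumin, LPS still raised part of the inflammatory genes. Cxcl2 rose at least 82.6-fold over curcumin alone (SE 0.34 on the log2 scale, n = 3 per group; adjusted p = 7.5e-07). Cxcl10 rose 98.5-fold, by 6.62 ± 0.35, the T cell chemokine gene Ccl5 by 5.83 ± 0.37, and the chemokine-binding receptor gene Ccrl2 by 5.25 ± 0.44. Tnf rose by 4.11 ± 0.46 and Isg15 by 4.31 ± 0.47. Il1b, Il6 and Ptgs2 were at 4.29 ± 0.82, 4.31 ± 0.91 and 3.25 ± 0.74 and did not pass (adjusted p = 0.0937, 0.173 and 0.236), and each of them passed without LPS+curcumin replicate 1 (adjusted p = 0.0305, 0.0085 and 0.0292). Il1b also passed with the slide as a block (adjusted p = 0.013).

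In limma 1130 genes and transcripts stood at an unadjusted p below 0.05, a share not far above the 0.05 that unchanged genes alone would give. After adjustment 41 changed, 39 higher and 2 lower, and 36 of the 41 were among the 717 that LPS raised without curcumin. On quantile scaling 30 were higher and 9 lower, and 17 higher calls held on all 5 scalings. The count was 16, 15 and 14 without curcumin replicates 1, 2 and 3, 72, 23 and 204 without LPS+curcumin replicates 1, 2 and 3, 68 with the slide as a block, and 10 with normexp. Of 20 named genes called, 9 were called whichever array was left out. The self-test recovered 72% of simulated 4-fold changes in this comparison.

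Of the 4 inflammatory lists, all higher at the preset correlation, the interferon list was not called with an estimated one (adjusted p = 0.15). Of 19 NF-kB genes 5 rose (16 adjusted over the list alone), with a median of 1.47 (camera, adjusted p = 6.7e-35), including Nfkbiz by 3.59 ± 0.32. Of 18 chemokines 6 rose (11 adjusted over the list alone), with a median of 1.80, or 0.49 with undetected genes at their bound (adjusted p = 2.17e-25). Of 25 cytokines and mediators 3 rose (12 adjusted over the list alone), with a median of 1.79, or 1.17 at their bounds (adjusted p = 3.11e-25). Of 38 interferon-stimulated genes 4 rose (8 adjusted over the list alone), with a median of 1.31, or 1.26 at their bounds (adjusted p = 8.15e-26). Within slides 1, 2 and 3 the median of the interferon-stimulated genes was 3.17, 0.34 and 0.42, and that of the cytokines 2.67, 0.68 and 1.14, slide 1 being that of LPS+curcumin replicate 1. With an estimated correlation the adjusted p = 0.0212 for NF-kB genes and for chemokines and 0.0348 for cytokines. Without LPS+curcumin replicate 1 the medians of NF-kB genes, chemokines, cytokines and interferon-stimulated genes were 1.104, 1.07, 1.21 and 0.33, with 6 genes of each list higher, and without replicate 3 of that group the last was 2.02. On spike-in scaling 2, 6, 2 and 2 genes were higher, calls that held on all 5 scalings. Oasl1, an interferon-stimulated gene, rose by 3.19 ± 0.33.

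Of 24 immediate early genes 2 rose (7 adjusted over the list alone), with a median of 0.45 (adjusted p = 5.87e-08, and adjusted p = 0.0539 with an estimated correlation). The NRF2 targets had a median of 0.13 with 0 of 32 called in limma, and the list was called higher (adjusted p = 0.00105, and 0.026 with an estimated correlation). Of 18 p53 targets 1 rose (4 adjusted over the list alone), and the list was called higher with a median of −0.02 and a mean of 0.32 (median 0.11 on spike-in scaling; adjusted p = 0.00477). TLR genes (median 0.25, adjusted p = 0.00157), ATF4 genes (0.17, adjusted p = 0.023) and genes of alternative activation (0.09, adjusted p = 0.0393) were called higher and DNA replication genes (−0.20, adjusted p = 0.0295) lower, with 0 members called in limma. On spike-in scaling the alternative activation and DNA replication lists were not called (adjusted p = 0.191 and 0.0937). With an estimated correlation the adjusted p = 0.0794, 0.494, 0.816, 0.412 and 0.816 for p53, TLR, ATF4, alternative activation and DNA replication genes. Without LPS+curcumin replicate 1 the lists of p53, TLR, alternative activation and DNA replication genes were not called (adjusted p = 0.0859, 0.816, 0.846 and 0.816), and the TLR median was −0.0017. The ATF4 call was lost without curcumin replicate 1 or 2 or LPS+curcumin replicate 3 (adjusted p of up to 0.547). That of DNA replication was also lost without curcumin replicate 1 or 3 or LPS+curcumin replicate 2, and that of alternative activation without curcumin replicate 2 or 3. Over single arrays left out the medians ran from −0.04 to 0.25 for NRF2, −0.06 to 0.29 for p53, −0.0017 to 0.64 for TLR, −0.21 to 0.26 for ATF4, −0.03 to 0.18 for alternative activation and −0.53 to 0.01 for DNA replication genes. The lowest NRF2, ATF4 and DNA replication medians were those without LPS+curcumin replicate 3. Nos2 did not pass (adjusted p = 0.869) and was not well above background on any curcumin array, so no size is given. Ccl2, Tlr2, Tlr4, Arg1, Hmox1 and Nqo1 did not pass, with changes of 1.39, 2.12, 0.15, −0.78, 0.31 and 0.36 and adjusted p from 0.766 to 0.961.

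The interaction asked whether curcumin acted differently in cells with and without LPS. Isg20 differed by −5.69 ± 0.33 (SE, n = 3 per group; adjusted p = 4.85e-05), Zbp1 by −6.61 ± 0.84, the vasoconstrictor gene Edn1 by −4.11 ± 0.46 and Dhx58 by −3.58 ± 0.43. The calls of Zbp1 and Dhx58 were lost on spike-in scaling (adjusted p = 0.0532 and 0.155). Csf3 was called too (adjusted p = 0.000481). It rose at least 9.49-fold with curcumin from background in untreated cells and fell by 6.23 with curcumin in LPS-treated cells. The interaction of Nos2 (adjusted p = 0.0115) rests on untreated and curcumin arrays at background, so neither its size nor its call is a measured difference. All of the 137 genes with a negative interaction were among the 717 that LPS raised. The interaction subtracts the LPS effect without curcumin, measured on the same arrays, so part of this overlap is built in. In limma 1282 genes stood at an unadjusted p below 0.05, a share not far above the 0.05 that unchanged genes alone would give. After adjustment 141 changed, 4 higher and 137 lower, against 72 on quantile and median scaling, 55 on spike-in scaling, 229 with the slide as a block and 2 with normexp. On all 5 scalings 1 higher and 47 lower calls held. The count was 90 and 80 without untreated replicates 2 and 3, 93, 92 and 78 without curcumin replicates 1, 2 and 3, 79 and 89 without LPS replicates 1 and 2, and 434 and 215 without LPS+curcumin replicates 1 and 3.

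Interferon-stimulated genes had a median interaction of −3.14, with 9 of 38 called lower (28 adjusted over the list alone; adjusted p = 4.96e-43), and −1.47, −4.14 and −4.66 within the slides. No bounds were set for the interaction, so medians of lists with undetected members, such as cytokines and chemokines, include values fitted against background. On spike-in scaling 1 of the 38 was called, the call that held on all 5 scalings, and without LPS+curcumin replicate 1 it was 33. Cytokines and mediators had −1.87 (4 of 25, 17 adjusted over the list alone; adjusted p = 2.17e-20), chemokines −1.99 (2 of 18, with 12 lower and 1 higher adjusted over the list alone; adjusted p = 4.21e-13), NF-kB genes −0.84 (0 of 19 in limma, 2 adjusted over the list alone; adjusted p = 7.77e-05) and antigen presentation genes −0.81 (1 of 18, 6 adjusted over the list alone; adjusted p = 2.59e-12). Adhesion genes had −0.36 (3 of 38, 6 lower and 1 higher adjusted over the list alone; adjusted p = 0.000934), which was 0.03 on spike-in scaling. On that scaling the medians were −2.71, −1.48, −1.60, −0.45 and −0.42 for interferon-stimulated genes, cytokines, chemokines, NF-kB and antigen presentation genes, with 1, 2, 2, 0 and 0 called in limma. With LPS+curcumin replicate 1 left out, 12 cytokines, 7 chemokines, 3 NF-kB, 4 antigen presentation and 5 adhesion genes were called lower, and the adhesion median was −0.18. Without LPS+curcumin replicate 3 the NF-kB list was not called (median −0.52, adjusted p = 0.157) and the adhesion median was −0.63. G2/M (0.14, adjusted p = 0.00633) and DNA replication genes (0.12, adjusted p = 0.00279; −0.19 on slide 1) were called higher with 0 members called in limma, and their medians were 0.52 and 0.56 on spike-in scaling. The G2/M call was lost without LPS replicate 2 or LPS+curcumin replicate 1 or 3 (median over single arrays left out 0.06 to 0.21, adjusted p of up to 0.142). The DNA replication call was lost without LPS+curcumin replicate 3 (median −0.12, adjusted p = 0.59), and its median was 0.45 without replicate 1 of that group. None of these 8 lists was called with an estimated correlation, where the adjusted p = 0.113 for interferon-stimulated genes, cytokines and chemokines, 0.132 for antigen presentation, 0.648 for NF-kB and G2/M, 0.744 for adhesion and 0.955 for DNA replication. The ATF4 list had a median of −0.16, or 0.23 on spike-in scaling, and was not called (adjusted p = 0.0983). It was called lower with the slide as a block (adjusted p = 0.0137) and without untreated replicate 3 or LPS replicate 1 (adjusted p = 0.00171 and 0.00556), and the TLR list without LPS+curcumin replicate 1 (median −0.51, adjusted p = 0.00027). Il1b and Il6 were at −5.74 ± 1.16 and −6.09 ± 1.29 (adjusted p = 0.055 and 0.0664), Il1b passing with the slide as a block (adjusted p = 0.0077) and both without LPS+curcumin replicate 1. Tnf, Ptgs2, Ccl2, Tlr2, Tlr4, Arg1, Hmox1 and Nqo1 were at −0.77, −2.68, −2.50, −0.50, 1.104, 0.10, −0.44 and 0.01, with adjusted p from 0.303 to 1.

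The 2 curcumin effects, measured on separate arrays, were similar across genes. Log2 fold changes with and without LPS correlated at r = 0.794 and rho = 0.804 over the 19314 genes, which are not independent replicates, and at 0.248, 0.786 and 0.850 within slides 1, 2 and 3. Between different slides, r was 0.727 to 0.777 with LPS+curcumin replicates 2 and 3, and 0.293 and 0.162 with replicate 1. Of genes called in both comparisons 1966 were higher in both (538 with independent calls), 503 lower in both (84.3 with independent calls), and 44 went in opposite directions. These counts are on the 75th percentile, where the medians of all genes were 0.41 and 0.32, a shift that adds to joint higher calls. On spike-in scaling lower calls outnumbered higher ones in both comparisons (8404 against 1395, and 2274 against 937). Joint counts are not given for that scaling. Hmox1, Trib3 and Colec11 were higher in both, and Tlr7, Irf8, Dusp6 and Hk2 lower in both, on all 5 scalings.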

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

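A test of the difference between the curcumin effects with and without LPS singled out 141 genes, and the lists and genes that follow. The list medians of this difference were −1.87 for inflammatory cytokines and mediators, −1.99 for chemokines, −0.84 for NF-kB subunits and feedback genes, −3.14 for interferon-stimulated genes, −0.81 for antigen presentation, 0.14 for G2/M genes, 0.12 for DNA replication and −0.36 for adhesion, migration and matrix genes, and on spike-in scaling −1.48, −1.60, −0.45, −2.71, −0.42, 0.52, 0.56 and 0.03 in this order. The genes were St6gal1 (2.10), Fhod1 (1.29), Hdc (−6.72), Zbp1 (−6.61), Batf2 (−6.18), Gbp5 (−5.83), Isg20 (−5.69), Csf3 (−11.36), Edn1 (−4.11), Nos2 (−6.19), Il1a (−6.76), Ccl8 (−4.19), Ccl12 (−5.28), Dhx58 (−3.58), Oas1a (−2.15), Ciita (−4.32), Nupr1 (−2.52), Mmp2 (−3.11), Mmp13 (−4.67), Mmp14 (−3.17) and Il1rn (−3.67). Csf3 was not well above background on any untreated array, and Nos2, Il1a, Ccl8, Mmp2 and Mmp14 on any untreated or curcumin array, so the values of these 6 genes are fitted against background and are not measured sizes. The medians of the cytokine, chemokine and adhesion lists include such values. None of the 8 lists was called with an estimated correlation (adjusted p from 0.113 to 0.955). Of the 21 genes, 10 were called whichever single array was left out, and 6 (Hdc, Isg20, Csf3, Edn1, Ccl8 and Mmp2) on all 5 scalings. The spike-in probes, which the comparisons themselves did not use, showed the 75th percentile 1.11 lower with curcumin than without treatment (−1.11 on the log2 scale).

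The tests of RNA from another tissue, of a mixture, of a label exchange and of the slide were chosen after the result was seen, as were the further versions of the test of neighbouring genes.

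Of 12996 genes and transcripts not well above background in untreated cells, 678 (5.22%) were well above it on all 3 curcumin arrays. Of the 678, 670 were called higher. The rises and bounds given here are on the 75th percentile and would be smaller on spike-in scaling. Negative control spots rose by 0.83 relative to the 75th percentile (0.0561 before scaling) and the 670 by a median of 4.18 (quartiles 3.36 and 5.25). The 670 were chosen for having risen, so setting their rise against that of the controls cannot weigh a raised background. The controls were not chosen by signal, and their 0.0561 lay within the SD of 3 arrays (0.136 untreated, 0.163 curcumin). The software had already subtracted background from this signal, so the controls cannot show a raised background that was subtracted. They show no rise at all spots after that subtraction, and one at single spots stays open. RNA from another tissue stays open: of fat transcripts undetected in untreated cells 66.7% (4 of 6: Adipoq, Ucp1, Cfd and Retn, up at least 42.4-fold, 43.0-fold, 2.23-fold and 3.45-fold, and not Lep and Car3) were detected on all curcumin arrays, against 30% in liver (3 of 10, with Alb up at least 28.5-fold and Ahsg at least 41.5-fold), 20% in testis (1 of 5), 14.3% in pancreas (1 of 7) and 0 of 4 in muscle, while 3 of 9 fat, 4 of 14 liver, 5 of 10 testis, 3 of 10 pancreas and 7 of 11 muscle transcripts were detected in untreated cells already. Expressed neighbouring genes stay open too: 82.7% of 312 genes that rose lay next to a gene detected in untreated cells, against 49.4% of 2528 that did not (odds ratio 4.89, 95% CI 3.59 to 6.75), with 3.75 (2.71 to 5.28) without clustered families and 13.2 (5.36 to 41.9) with both neighbours on the array. A hypothesis is that curcumin may lead to transcription running from expressed genes into neighbours, which reads of known strand would test.

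LPS+curcumin replicate 1 stood apart from the other 2 arrays of its group. A mixture of LPS-only RNA with LPS+curcumin RNA is argued against, since it would give every gene the same share of the curcumin response, and the array showed a median of 61.0% for 12 NRF2 targets (quartiles 28.9 and 101), 78.8% for 37 lower interferon-stimulated genes (63.3 and 86.5) and 1.60% for 650 genes undetected in untreated cells (0.191 and 8.36). A label exchanged with an LPS array is argued against by Hmox1, which lay 2.71 above the highest LPS array. Its slide is argued against, since the curcumin array of that slide lay 0.404 below the other 2 curcumin arrays over the 713 genes concerned, and this array 3.05 below the other 2. A lower or shorter exposure to curcumin may give such an array and was not tested.

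LPS-induced genes were lower with curcumin. Scaling is argued against as the whole cause, since their median change was at most −0.68 over the alternatives (with normexp; −1.40 on the 75th percentile, −1.75 on quantile, −2.13 on median, −2.12 on spike-in and −1.39 on always detected probes; SD 0.271 over slides). In each of 20 simulations without a curcumin effect 0 induced genes were called lower in limma, against 430 observed. That count cannot weigh selection on the shared LPS arrays, since no simulated gene differed between LPS+curcumin and LPS and the adjustment then leaves few calls. The median change of the induced genes averaged −0.089 in these simulations, against −1.40 observed. That argues against selection as the whole cause. A biological effect of curcumin on the LPS response remains as a hypothesis, found and tested on the same arrays, and position on the slide is confounded with group. Lower Tlr4 signal with curcumin alone may contribute, which was not tested.

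The 10 splits of 6 arrays are too few for a share under 0.05. The real split, 1 of 10 with as many genes, gave 1107 genes for LPS versus untreated (highest other 0), 5632 for curcumin versus untreated (0), 3618 for LPS+curcumin versus LPS (11) and 41 for LPS+curcumin versus curcumin (1). For the interaction, 4 of 100 drawn splits (200 possible), the real one included, gave at least 141 genes. The highest other gave 10178, and the 3 others with as many exchange labels between LPS and LPS+curcumin arrays only, so that they take in the curcumin effect itself, which is a structure of these samples.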

How the results depend on the processing

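The cause of the differences between alternatives was not tested. Of 1135 values of called lists over the alternatives, 1020 kept the call, 111 lost it and 4 were reversed, and of 7290 values of called genes these were 5624, 1618 and 48. The replicate number is also the slide. Of 18 pairs of arrays on a slide, 16 had residuals correlating above 0.1 (lowest −0.0191, highest 0.713; median 0.242 against −0.176 between slides). A shared batch and paired samples would both give this, and they cannot be told apart, since replicate number, slide and scan coincide. With the slide as a block the interaction of Ciita (adjusted p = 0.074) and of Fhod1 (adjusted p = 0.0505) was no longer called, and apart from these and the changes stated beside the results the block changed no call of a named gene or list. A fit without a whole replicate leaves 2 arrays per group. The filter on all 12 arrays gives values for 244 of the 359 results on named genes, and fits of only the groups compared give 328, since the interaction needs all groups.

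Normexp gave 197 genes for LPS versus untreated, 872 for curcumin versus untreated, 89 for LPS+curcumin versus LPS, 10 for LPS+curcumin versus curcumin and 2 for the interaction, with 62 induced genes lower, 1 reduced gene higher, and 18 lists called in LPS+curcumin versus curcumin. Quantile normalization gave 72 for the interaction, 41 reduced genes higher and 3 lists for curcumin versus untreated. Scaling on the median gave 660 for LPS versus untreated, 24 for LPS+curcumin versus curcumin, 72 for the interaction, 30 reduced genes higher and 3 lists for curcumin versus untreated. Scaling on spike-in probes gave 653, 9799 (curcumin versus untreated), 20 and 55 in that order, and 31 reduced genes higher. With no filter 39 reduced genes were higher and 14 lists were called for curcumin versus untreated, and with the filter on all 12 arrays the interaction had 73 genes and curcumin versus untreated 3 lists, as with the mean over probes (3 lists). The block gave 5575 for LPS+curcumin versus LPS, 68 for LPS+curcumin versus curcumin, 229 for the interaction and 108 reduced genes higher. Fits of only the groups compared gave 2396, 10541, 302 and 6 genes for the first 4 comparisons.

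Leaving out each array or replicate in turn gave 198 to 1814 genes for LPS versus untreated, 20 to 9694 for curcumin versus untreated, 9 to 10789 for LPS+curcumin versus LPS, 4 to 204 for LPS+curcumin versus curcumin and 0 to 434 for the interaction. It gave 6 to 635 induced genes lower, 0 to 163 reduced genes higher, a slope of 0.183 to 0.335 and an r of the curcumin effects of 0.669 to 0.843. Lists called were 10 to 13, 3 to 6, 7 to 14, 9 to 12 and 5 to 10 (single arrays were left out for the lists after the data were seen), and 8 for LPS+curcumin versus LPS without LPS+curcumin replicate 1.

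Directions were reversed with normexp for the median of NRF2 targets in curcumin versus untreated (−0.0054) and of DNA replication genes in LPS+curcumin versus curcumin (0.45). Single genes reversed with normexp were, in curcumin versus untreated, Rtn4rl1 0.70, Tlr3 1.16, Kynu 1.27, Pdcd1 1.28, Bst2 −0.0922, H2-T23 −0.11, H2-D1 −0.19, Hspa5 −0.071, Calr −0.0473, Rac2 −0.0497, P2ry13 0.77, Slc11a1 −0.16 and Aldoc −0.0629, in LPS+curcumin versus LPS Mmp2 0.31 and P2ry13 0.16, and in LPS+curcumin versus curcumin Heatr9 −0.52 and Edn1 −0.38. In curcumin versus untreated, quantile normalization reversed Cd79a −0.13, the mean over probes Slc39a14 −0.11, and scaling on the median Oas1a −0.0984, Bst2 −0.14, H2-T23 −0.19, H2-D1 −0.17, Hspa4l −0.12, Hspa5 −0.15, Calr −0.0875, Rac2 −0.0744, Slc11a1 −0.20 and Aldoc −0.0661. Scaling on spike-in probes reversed Nfkbib −0.0128, Sod2 −0.25, Oas1a −0.37, Bst2 −0.41, H2-T23 −0.46, H2-D1 −0.44, Hspa4l −0.39, Hsp90ab1 −0.20, Slc3a2 −0.14, Hspa5 −0.42, Calr −0.36, Rac2 −0.34, P4ha1 −0.23, Pgk1 −0.25, Slc11a1 −0.47, Aldoc −0.33, Lck −0.18, Cd79a −0.13 and Cd3e −0.19, and turned the test of the interferon-stimulated genes (median −1.42). Without LPS+curcumin replicate 1, the median of TLR genes in LPS+curcumin versus curcumin was reversed (−0.0017), with 0.64 without LPS+curcumin replicate 3 as the highest value when leaving out arrays.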

Other observations

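The lists of DNA replication, cholesterol synthesis, LXR, glycolysis, metallothionein, p53, alternative activation and adhesion genes were not called with curcumin alone on the 75th percentile, and their medians lay lower on spike-in scaling. The member counts below stand against all 19314 genes and transcripts, of which 4226 were higher on the 75th percentile and 8404 lower on spike-in scaling. There, DNA replication genes were called lower (16 of 25 lower, median −0.70, adjusted p = 0.0362), against 3 of 25 lower (3 on all 5 scalings), a median of 0.41 and adjusted p = 0.644 on the 75th percentile. Of 23 cholesterol synthesis genes 3 rose and 2 fell (2 lower calls on all 5 scalings; list adjusted p = 0.406; 13 lower on spike-in scaling, median −0.75), among the latter the sterol synthesis gene Hmgcs1 by −2.09 ± 0.42 (SE, n = 3 per group). Of 13 LXR targets 1 rose, Smpdl3a at least 22.5-fold, and 1 fell (both calls on all 5 scalings; adjusted p = 0.158; 9 lower on spike-in scaling, median −1.22). Of 25 glycolysis and hypoxia genes 4 rose and 2 fell (2 lower calls on all 5 scalings, adjusted p = 0.503, and 15 lower on spike-in scaling, median −0.85), the latter the hexokinase gene Hk2 by −1.45 ± 0.22 and Ankrd37 by −1.25 ± 0.25. Of 13 metallothionein and metal genes 3 rose (1 on all 5 scalings, adjusted p = 0.543, and 1 higher and 5 lower on spike-in scaling), the iron hormone gene Hamp at least 11.1-fold. Of 18 p53 targets 6 rose and 3 fell (2 lower calls on all 5 scalings, adjusted p = 0.94, and 7 lower on spike-in scaling). Of 24 genes of alternative activation 3 rose and 2 fell (2 lower calls on all 5 scalings, adjusted p = 0.341, and 6 lower on spike-in scaling), and of 38 adhesion genes 4 rose and 3 fell (1 and 3 on all 5 scalings, adjusted p = 0.349, and 1 higher and 21 lower on spike-in scaling). The calls of Hmgcs1, Smpdl3a, Hk2, Ankrd37 and Hamp held on all 5 scalings.

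Markers of other cells were followed as well. With curcumin alone, 4 of 6 lymphocyte, 2 of 3 astrocyte and 1 of 3 neuron markers were called higher on the 75th percentile, with medians of 0.92, 0.77 and 1.04, and none of them on spike-in scaling, where the medians were −0.18, −0.33 and −0.07 and 1 astrocyte marker was lower. The endothelial gene Pecam1, 1 of 6 fibroblast and endothelial markers called, rose at least 15.5-fold on the 75th percentile, a call that held on all 5 scalings, and no oligodendrocyte marker of 5 was called higher on either. The list adjusted p was 0.127, 0.503, 0.406, 0.713 and 0.808 for lymphocyte, astrocyte, neuron, fibroblast and endothelial, and oligodendrocyte markers. In LPS+curcumin versus LPS the list adjusted p was 0.204, 0.346, 0.36, 0.821 and 0.954 in this order, and with LPS alone 0.44, 0.458, 0.677, 0.658 and 0.518. In LPS+curcumin versus LPS the lists of cholesterol synthesis, LXR, G2/M, DNA replication, p53, alternative activation, glycolysis and metallothionein genes had adjusted p = 0.188, 0.158, 0.588, 0.188, 0.743, 0.28, 0.28 and 0.899. On spike-in scaling the G2/M list was called lower there (median −0.62, adjusted p = 0.0395). Without LPS+curcumin replicate 3 camera called the cholesterol list (median −0.30, adjusted p = 0.00149) and the glycolysis list (−0.06, adjusted p = 0.0203) lower there. With LPS alone NRF2 targets (3 of 32 higher), heat shock, endoplasmic reticulum, cholesterol, LXR, p53 (6 of 18 higher, 1 lower), alternative activation (5 of 24 higher, 2 lower), identity (3 of 26 lower), glycolysis and metallothionein genes had adjusted p = 0.086, 0.658, 0.813, 0.738, 0.295, 0.178, 0.376, 0.0813, 0.863 and 0.158. Identity genes were called lower in camera without untreated replicate 2 or 3 or LPS replicate 1 (lowest median −0.40, adjusted p from 0.00234 to 0.029). LXR targets were called lower without untreated replicate 3 or LPS replicate 1 (median −0.38 and −0.23, camera adjusted p = 0.0341 and 0.0476). The lists not named for LPS+curcumin versus curcumin had adjusted p from 0.154 to 0.722, and those for the interaction from 0.0983 to 0.96. With single arrays left out, camera called some in LPS+curcumin versus curcumin (adjusted p from 0.00677 to 0.0488). Without LPS+curcumin replicate 1 heat shock and lymphocyte genes were higher and LXR and identity genes lower. Without curcumin replicate 3 chaperones were higher and LXR and identity genes lower. Cholesterol genes were lower without curcumin replicate 2 or LPS+curcumin replicate 3, and adhesion genes higher without LPS+curcumin replicate 2.

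Of genes undetected in untreated cells, 9.13% of those with a symbol (429 of 4699) and 3.00% of those without (249 of 8297) were detected on all 3 curcumin arrays. The lipid droplet gene Plin1, with signal in untreated cells, rose with curcumin in LPS-treated cells by 4.26 ± 0.53, while the fat gene Elovl3, chosen after its values were seen, lay within 0.005 of its untreated level with curcumin alone. The scale of the arrays themselves moved with curcumin, and whether less RNA per cell or less labelled material lay behind this was not tested.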
